A study of Arabidopsis thaliana with 6 samples.

How the data were processed

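Nuclei were isolated from whole siliques, sorted by DAPI staining and profiled with the 10x Chromium Next GEM 3' chemistry, per the labels' protocols. Each of the 6 libraries gave a matrix of UMI counts per gene and barcode, made with Cell Ranger 7.2.0 per the file headers and deposited by the authors without normalization. The genome build was TAIR10, per the submitters' processing notes. The release of the gene models and whether intronic reads were counted are not given in the sources used here. The matrices hold 27628 gene codes and 31830 barcodes, a called subset of droplets. Gene codes were matched to an NCBI annotation of the TAIR10.1 assembly for names only: 27420 matched and 10361 had a symbol. LHP1 stands under the symbol TFL2 there and was taken by its code. No coordinates were used. Groups came from the sample titles. The titles name lhp1 and the series design a homozygous lhp1-6 line, while the genotype label of all 6 samples reads Col-0, so the LHP1 gene itself was read first.

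Barcodes were kept with at least 200 genes and at most 10% of UMIs from the 208 organelle-encoded genes, which were left out of all tests. The gene minimum removed 357 barcodes, all in replicate 2 of Col-0 at 22 °C, and the organelle limit 10, 16, 14, 3, 6 and 16 in Col-0 at 16 °C, Col-0 at 22 °C and lhp1 by replicate. Doublets were scored with scrublet in scanpy 1.11.5. Its automatic threshold marked between 0% and 2.40% of barcodes per library and was not used. The highest-scoring nuclei up to 0.8% per 1000 barcodes were removed instead, which came to 333, 210, 299, 99, 246 and 200. In all 30021 nuclei were kept. Organelle-encoded UMIs made up 1.39% and 1.48% of the libraries of Col-0 at 16 °C, 1.69% and 2.94% at 22 °C, and 1.47% and 1.30% in lhp1.

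Nuclei of all libraries were clustered together, with no batch integration, on 2000 variable genes, log values of UMIs per 10000, 30 principal components, 15 nearest neighbours and Leiden resolution 1 (leidenalg 0.10.2, scikit-learn 1.9.0). A cluster was named after 1 of 11 marker lists (147 codes) if at least 3 markers lay among its 500 leading genes with a hypergeometric p under 0.01. It stayed a number where another list had more markers that were higher, or more among the 10 leading genes. The marker lists were embryo, endosperm, seed coat, fruit mesophyll, epidermis, guard cell, phloem, xylem and cambium, lignified layers and valve margin, dividing cell, and replum. The marker lists were fixed in advance but the naming thresholds were not. The index of spread between barcodes is the mean squared deviation of a gene's counts from a common profile over its counting variance, with a median over the 300 most abundant genes. It was also taken with each barcode thinned to 400 UMIs.

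Raw UMI counts of the kept nuclei were summed per library, and per library and class. Sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05), for Col-0 at 22 °C against 16 °C and for lhp1 against Col-0 at 16 °C, with all groups in 1 fit and no block. The standard error is the log2 fold change over the root of the F statistic. The planned class-level fit over 6 libraries could be made for no class, since replicate 2 of Col-0 at 22 °C held under 20 nuclei of each. The class-level fit was therefore changed, after the data were seen, to the other 5 libraries and classes or clusters with at least 20 nuclei in each. A class-by-group test with the library as a block covered 9 classes. Shares of nuclei were tested in the same tool. CPM values carry TMM scaling. Intervals are exact at 95% and, like the floor of 3 counts over a group, cover counting error only. Total UMIs per library and the nuclei behind each class set the precision of the values.

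The 17 gene lists (257 codes) were ABA synthesis, ABA catabolism, ABA transport, ABA signalling, dormancy regulators, gibberellin, cold response, heat response, thermomorphogenesis, flavonoid pathway, seed storage and late embryogenesis, floral and flowering regulators kept silent by Polycomb, Polycomb and antagonists, photosynthesis, circadian clock, wound and touch, and senescence. They were tested with camera and fry in limma 3.58.1 on voom values, and 2 members whose reference name contradicted the list were left out. Pollen, suberin and sugar starvation lists were written after leading genes had been seen. Samples, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The rule took LHP1, up to 6 genes with the largest rise and 6 with the largest fall over whole libraries among called genes of at least 10 CPM with no overlap between libraries (if none was called, the 4 with the smallest p), 3 genes each way per class by p, up to 4 members per list, and DOG1, MFT, NCED6, NCED9, CYP707A1, CYP707A2, ABCG25, ABCG40, ABCG30, ABCG31 and FT. The text gives part of the genes the rule takes.

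The tests were tried on simulated data with the libraries' own means, depths and spread, and 100 genes changed at each fold size. The changed genes were drawn from those of at least 10 CPM on average, so recovery of weaker genes was not simulated. Over whole libraries 76% of 4-fold and 4% of 2-fold changes were called in each comparison, and 7 of 87 and 8 of 88 calls were false (19046 and 19069 genes). For embryo-like nuclei 73% and 29% were called for temperature and 92% and 46% for lhp1, with 17 of 119 and 14 of 152 calls false (14616 and 14585 genes). For phloem-like nuclei these were 57% and 3%, and 65% and 20%, with 1 of 61 and 4 of 89 false (2664 and 2645 genes). False calls were thus above the nominal 0.05 in some of these tests.

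Alternatives were a replicate block, DESeq2 1.42.0, its size factors in edgeR, library totals, no or a stricter count filter, only the groups compared, each library left out, at least 400 genes per nucleus, no doublet removal, all deposited barcodes, thinned counts, equal nuclei, and Leiden resolutions 0.5 and 2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.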

Results

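Single-nucleus RNA sequencing was carried out on whole siliques, the fruits of Arabidopsis thaliana, with the seeds inside them, at the stage when the cotyledons of the embryo bend over. Plants of the accession Col-0 and of the mutant lhp1 were grown in long days at 16 °C by day and 14 °C by night. The Col-0 plants of 1 group were moved to 22 °C for a single day, with the aim that stages matched. Whether the seeds of the groups were at the same stage was not tested. LHP1 codes for a chromodomain protein that binds histone marks set by the Polycomb repressive complex. The 3 groups, Col-0 at 16 °C, Col-0 at 22 °C and lhp1 at 16 °C, had 2 libraries each. The question named by the series title concerns how the temperature met by the mother plant acts on her progeny, and hormone movement. The libraries held 9081320 and 6446880 unique molecular identifiers (UMIs) in Col-0 at 16 °C, 9448079 and 1773191 at 22 °C, and 7858018 and 9905984 in lhp1, for replicates 1 and 2. After filtering, 6128, 4904, 5803, 3066, 5299 and 4821 nuclei remained, in the same order, with median UMI counts of 1096.5, 1020.5, 1253, 417, 1159 and 1636. Nothing in the labels says whether the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

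In replicate 2 of Col-0 at 22 °C, 3053 of 3066 nuclei fell into 1 cluster that held 49 nuclei of the other 5 libraries together, and no named cell class had 20 nuclei there. The counts of a gene varied between its barcodes with a median index of 1.07 over the 300 most abundant genes, where 1 is counting error alone, against 2.46 to 3.55 in the other libraries. All class-level values therefore come from 5 libraries, with replicate 1 as the only library at 22 °C, a choice made after the data were seen. The class-level temperature values compare this library with 2 libraries of Col-0 at 16 °C, and it is assumed to vary as the other groups do.

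Embryo-like nuclei were 10.3% ± 2.62 (SD, n = 2) of the kept nuclei in Col-0 at 16 °C, 14.7% ± 0.726 in lhp1 and 8.62% in the library at 22 °C. Endosperm-like nuclei, from the tissue that feeds the embryo, made up 6.04% ± 2.40, 8.02% ± 0.0463 and 2.58%, in the same order. Seed coat-like nuclei made up 12.1% ± 3.74, 9.42% ± 4.54 and 5.53%, and fruit mesophyll-like nuclei, from the green fruit wall, 14.6% ± 7.03, 20.96% ± 0.752 and 12.2%. Epidermis-like, guard cell-like, phloem-like, xylem and cambium-like and dividing cell-like nuclei were scarcer, at 2.71% ± 0.228, 3.06% ± 0.109, 1.51% ± 0.0573, 0.953% ± 0.568 and 1.23% ± 0.845 in Col-0 at 16 °C. No class differed in share between groups in edgeR's quasi-likelihood test on nuclei, where the smallest Benjamini-Hochberg adjusted p values were 0.554 for temperature and 0.647 for lhp1. Other groups of nuclei stayed numbers, most of them with too few markers for a name. Clusters 12, 15 and 19 had enough markers, 11 of embryo, 3 of epidermis, and 4 of xylem and cambium. They were not named because another list had more markers among the leading genes, or in cluster 19 more that were higher. Cluster 12 held 3.80% ± 0.725 of the nuclei in Col-0 at 16 °C. Cluster 1, near the seed coat list, held 15.04% ± 2.70 in Col-0 at 16 °C, 5.71% ± 4.52 in lhp1 and 11.2% at 22 °C. Clusters 9 and 24, near the endosperm list, held 4.17% ± 2.41 and 0.640% ± 0.271, 5.47% ± 1.01 and 2.24% ± 1.44, and 1.72% and 0.258%. Thresholds set after the data were seen kept clusters 1, 9 and 24 out of the classes. Clusters 11 and 14, led by FAR4, a fatty acyl reductase gene of suberin synthesis, and the laccase gene LAC12, held 0 and 8 nuclei in replicate 1 of Col-0 at 16 °C, 518 and 346 in replicate 2, 528 and 521 at 22 °C, and 29 and 62, and 5 and 9, in the lhp1 libraries. With 2 libraries against 2, an exact two-sided permutation test could not reach a p under 0.05.

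**Figure D1:**
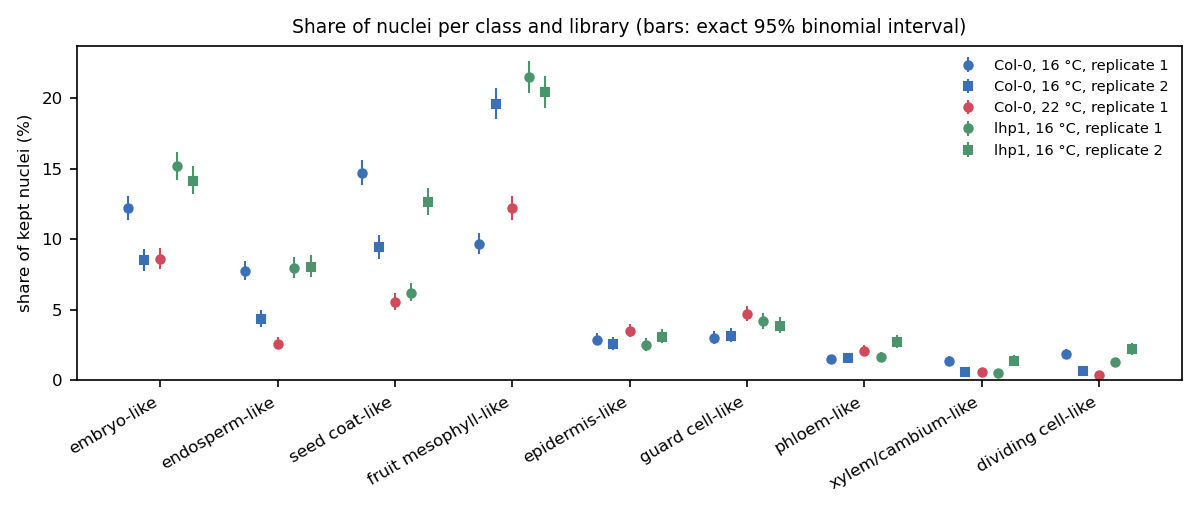
Share of kept nuclei (vertical axis, percent) in each of 9 classes (horizontal axis) for the 5 libraries with recognisable nuclei. Points are libraries, circles replicate 1 and squares replicate 2, coloured by group, and bars are exact 95% binomial intervals, which cover counting error only. Fruit mesophyll-like nuclei spread from 9.68% to 19.6% between the Col-0 libraries at 16 °C.

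The gene named by the mutant was examined first. LHP1 (AT5G17690) had 410 and 267 UMIs in Col-0 at 16 °C, 415 and 56 at 22 °C, and 72 and 83 in lhp1. These are 48.4 and 45.7, 50.7 and 37.2, and 10.0 and 8.53 CPM, which are UMI counts scaled to a common library size. Its log2 fold change in lhp1 was -2.34 ± 0.23 (SE, 2 libraries against 2, lower in both), with a Benjamini-Hochberg adjusted p of 0.0241 in edgeR's quasi-likelihood test over 19304 genes. Within classes LHP1 fell by 2.18 ± 0.29 in embryo-like, 3.53 ± 0.43 in endosperm-like and 3.50 ± 0.58 in fruit mesophyll-like nuclei on the log2 scale (edgeR, adjusted p = 0.00109, 0.000533 and 0.0137, Benjamini-Hochberg). In seed coat-like nuclei the log2 fold change of -1.36 ± 0.29 did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.121). Between Col-0 at 22 and 16 °C it was -0.08 ± 0.22 over whole libraries. The whole-library call was lost in the fits without replicate 2 of Col-0 at 16 °C (-2.39), without replicate 1 or 2 of Col-0 at 22 °C (-2.35 each) and without replicate 1 or 2 of lhp1 (-2.46 and -2.24). The fruit mesophyll-like call was lost without replicate 2 of Col-0 at 16 °C (-2.71) and at a clustering resolution of 2 (-3.87). DESeq2 gave LHP1 no adjusted p in endosperm-like nuclei (-3.59).

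Between whole libraries at 22 °C and 16 °C, the genes with the smallest p were AT5G54585, AT5G05965, AT3G15450 and AT2G15960, all higher in both libraries at 22 °C and none past the threshold. The whole-library group at 22 °C includes replicate 2, whose barcodes hardly differed from one another. AT3G15450 stood at 31.1 CPM at 16 °C and 249 CPM at 22 °C, a log2 fold change of 3.001 ± 0.28 (SE, n = 2 libraries per group). AT5G54585 stood at 14.9 and 83.2 CPM, with 2.49 ± 0.20, AT2G15960 at 13.9 and 72.6 CPM, with 2.37 ± 0.23, and AT5G05965 at 0.263 and 16.5 CPM, with 5.83 ± 0.52. All 4 had a Benjamini-Hochberg adjusted p of 0.0745 in edgeR's quasi-likelihood test. That test called 0 of 19304 genes, with 3508 at an unadjusted p under 0.05, while DESeq2 called 489 higher and 355 lower. In simulated libraries of the same depth and spread, with 19046 genes tested, changed genes were drawn only from those of at least 10 CPM on average. Of these, 76% of genes changed by 4-fold and 4% of those changed by 2-fold were called for this comparison. Recovery of weaker genes was not simulated. Without replicate 2 of Col-0 at 16 °C, edgeR called 434 genes; this library correlated better with replicate 1 at 22 °C (Pearson r = 0.934 across 13906 genes, which are not independent) than with replicate 1 at 16 °C (0.863).

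Several gene lists leaned one way between the whole libraries, which again included replicate 2 at 22 °C. Members of the seed storage and late embryogenesis list, which holds 2S albumins, cruciferins, oleosins and late embryogenesis abundant proteins, had a median log2 fold change of 1.28 at 22 °C over 18 genes (camera with a preset correlation, Benjamini-Hochberg adjusted p = 1.56e-06). Photosynthesis genes had a median of 0.92 over 11 (3.74e-04), wound and touch genes 0.91 over 10 (0.0178), and abscisic acid (ABA) signalling genes 0.37 over 22 (0.0143) in the same test. The medians of the Polycomb list, -0.53 over 17 genes (7.12e-04), and of the flavonoid list, -0.50 over 14 (0.0109), lay below 0. None of these calls was kept with an estimated correlation, where the adjusted p was 0.555 for each list but wound and touch, with 0.702. Marker medians were 1.23 for embryo, 0.90 for fruit mesophyll, -0.65 for seed coat and -1.29 for dividing cell markers. Camera gave adjusted p of 0.00360, 3.74e-04, 7.12e-04 and 0.0143 with the preset and 0.555, 0.555, 0.555 and 0.616 with an estimated correlation (Benjamini-Hochberg). The embryo, fruit mesophyll and seed coat lists share genes with the storage, photosynthesis and flavonoid lists, so they are no independent reading. All 11 photosynthesis genes are fruit mesophyll markers. Embryo-like and fruit mesophyll-like nuclei were not a larger share in replicate 1 at 22 °C (8.62% and 12.2%) than at 16 °C (10.3% and 14.6%). Seed coat-like and dividing cell-like nuclei, at 5.53% and 0.379% against 12.1% and 1.23%, went the way of their markers. Without replicate 1 at 22 °C or without replicate 2 at 16 °C, the ABA signalling, flavonoid and wound and touch calls were lost. The dividing cell call was lost without replicate 1 of either Col-0 group, and the embryo call without replicate 2 at 22 °C. The other lists did not pass with the preset correlation. Their medians were -0.20 for ABA synthesis, 0.43 for ABA catabolism, -0.43 for ABA transport, -0.30 for dormancy regulators, 0.10 for gibberellin genes, 0.28 for cold response, -0.26 for heat response and 0.45 for thermomorphogenesis. They were 0.13 for floral and flowering regulators silenced by Polycomb, 0.03 for the circadian clock and 0.19 for senescence. For the remaining markers they were -0.93 for endosperm, 0.13 for epidermis, 0.94 for guard cell, 0.57 for phloem, -0.89 for xylem and cambium, -0.48 for lignified layers and 0.01 for replum. The adjusted p of these 18 lists ran from 0.0511 to 0.959.

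In embryo-like nuclei, 1 of 9 measured dormancy regulators, 2 of 20 ABA signalling genes and 1 of 3 ABA catabolism genes rose at 22 °C. Camera gave the first list a Benjamini-Hochberg adjusted p of 0.325 and the second 0.00417 with the preset correlation, and adjusted p of 0.635 and 0.610 with an estimated correlation. DOG1 (AT5G45830), which sets the depth of seed dormancy, had 82.5 and 130 CPM in the libraries at 16 °C and 284 CPM at 22 °C, a log2 fold change of 1.47 ± 0.29 (SE, 1 library against 2). ABF4, a transcription factor of the ABA pathway, rose from 42.4 to 158 CPM (1.90 ± 0.24), AHG1, a phosphatase that restrains ABA signalling in seeds, from 20.04 to 71.9 CPM (1.95 ± 0.37), and CYP707A2, which breaks down ABA, from 18.7 to 64.4 CPM (1.79 ± 0.34). Their Benjamini-Hochberg adjusted p values in edgeR's quasi-likelihood test were 0.0257, 0.00138, 0.0219 and 0.0219. The clock gene LNK2 rose by 1.36 ± 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.0120). Adjusted over the list alone, 4 of the ABA signalling genes rose. RD29B and RAB18, markers of ABA response, had log2 fold changes of 1.71 ± 0.41 and 2.35 ± 0.60 and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.0587 and 0.0748). All 17 measured seed storage and late embryogenesis genes had positive log2 fold changes, with a median of 0.84, but 1 passed and 6 passed adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.90e-11 with the preset and 0.610 with an estimated correlation). The class joined clusters 4 and 7, and cluster 7, with 2S albumin and cruciferin genes among its markers, held 285 of 747 and 213 of 416 of its nuclei at 16 °C, 275 of 500 at 22 °C, and 262 of 804 and 210 of 682 in lhp1. CRU3 and CRU2, which code for 12S globulins, differed between the libraries at 16 °C, with 1074 and 3020 CPM for CRU3 against 4519 CPM at 22 °C. Whether the seeds at 22 °C were at a later stage was not tested. In this and the other classes, a difference in stage therefore cannot be told apart from an effect of temperature.

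Over all genes, 118 rose and 29 fell in embryo-like nuclei of 15046 tested. The 3 with the smallest p among those that rose were AT5G05965, AT1G27990 (3.70 ± 0.37) and AT3G14330 (2.06 ± 0.25), with edgeR Benjamini-Hochberg adjusted p of 2.10e-05, 2.34e-04 and 0.00137. AT5G05965 had 1 UMI at 16 °C and 103 at 22 °C, a ratio of 189 with a 95% counting interval of 33.3 to 7556. LTP4, a lipid transfer protein, fell by 2.05 ± 0.30 and LNG1, which promotes cell elongation, by 2.38 ± 0.38 (edgeR, Benjamini-Hochberg adjusted p = 0.00309 and 0.00615). The count of 147 was 294 without replicate 1 and 684 without replicate 2 of Col-0 at 16 °C, and 451 and 381 without replicates 1 and 2 of lhp1. It was 76 with doublets kept and 80 and 79 at clustering resolutions of 0.5 and 2, where DOG1 was not called (1.45, 1.55 and 1.4801, in that order), nor LNG1 at 0.5 (-1.46). DESeq2 called 21 higher and 7 lower, without DOG1, AHG1, CYP707A2, LNG1 or AT5G05965, and AHG1 lost its call without replicate 1 of Col-0 at 16 °C (1.46).

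Endosperm-like nuclei had 50 genes higher and 28 lower at 22 °C of 10449. AT1G23660 rose from 16.8 to 322 CPM (log2 fold change 4.38 ± 0.39), and the late embryogenesis gene ECP63 from 188 to 701 CPM (1.86 ± 0.28). The RNA-binding protein gene GRP7, which also answers to cold, rose by 1.02 ± 0.23 and CAB1, for a light-harvesting protein, by 1.31 ± 0.30. REV, a transcription factor of leaf polarity and vascular tissue, fell by 2.47 ± 0.40, iqd15 by 3.30 ± 0.47 and AT1G11070 by 2.28 ± 0.33. Adjusted p values were 2.49e-05, 0.00565, 0.0448, 0.0491, 0.00845, 0.00416 and 0.00428 (edgeR quasi-likelihood, Benjamini-Hochberg). Storage and late embryogenesis genes were positive in 13 of 14 members, of which 1 passed and 3 passed adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.96e-07 with the preset and 0.497 with an estimated correlation). Cluster 22 of this class, with LEA7 among its leading genes, held 97 of 474 and 51 of 213 of its nuclei at 16 °C and 57 of 150 at 22 °C. DESeq2 called 24 genes, without CAB1. The count of 78 was 15 with at least 400 genes per nucleus, where ECP63 (1.43), GRP7 (0.62), CAB1 (1.08), REV (-0.72) and iqd15 (-1.9988) were not called, 21 with equal nuclei per library, and 14 without replicate 1 of Col-0 at 16 °C, and 282 and 283 without replicates 1 and 2 of lhp1. GRP7 lost its call without either Col-0 library at 16 °C (0.997 and 1.09) and CAB1 without replicate 1 (0.93), and with doublets kept GRP7 (0.66), CAB1 (1.01) and REV (-0.78) lost theirs. At a clustering resolution of 2, GRP7 (0.86), CAB1 (1.16) and REV (-1.98) were not called. GRP7 and CAB1 also lost their calls with equal nuclei (1.03 and 1.28) and with the strict low-count filter (1.04 and 1.33), GRP7 at a resolution of 0.5 (1.03) and CAB1 with library totals (1.31).

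In dividing cell-like nuclei, of which the library at 22 °C held 22, 5 of 14 measured seed storage and late embryogenesis genes rose at 22 °C, and 9 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.87e-23 with the preset and 0.663 with an estimated correlation). CRU3 rose from 166 to 2398 CPM (log2 fold change 3.66 ± 0.40), CRU2 from 328 to 1421 CPM (2.199 ± 0.41) and SESA2, a 2S albumin gene, by 2.25 ± 0.48. These 3 genes are also markers of embryo-like nuclei. The test of a difference between classes did not pass for CRU3 (edgeR, Benjamini-Hochberg adjusted p = 0.170). AT1G76780 fell by 2.92 ± 0.63, and APL4, a subunit of the enzyme that makes ADP-glucose for starch, had 0 UMIs at 22 °C against 65 at 16 °C, at least 4.49-fold lower with 3 counts over the group as the floor. In edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 1.42e-16 for CRU3, 1.09e-04 for CRU2, 0.00259 for SESA2 and AT1G76780 and 0.00334 for APL4, while DESeq2 called 0 of the 4780 genes, 483 of which had an unadjusted p under 0.05 in edgeR. In all, 15 genes rose and 11 fell. The count of 26 was 4 with equal nuclei per library, where CRU2 (2.104), SESA2 (2.08), AT1G76780 (-2.16) and APL4 were not called, and 6 with thinned counts. APL4 also lost its call with doublets kept (-2.77) and at a clustering resolution of 0.5 (-1.71), and SESA2 in both (2.05 and 1.9962), with thinned counts (1.60), without replicate 1 of Col-0 at 16 °C (1.82), and with no or a strict low-count filter (2.07 and 2.08), where the class had 8 and 9 calls.

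In phloem-like nuclei, RD29A, a gene induced by cold and ABA, had 118 UMIs at 16 °C and 0 at 22 °C. It was at least 36.1-fold lower at 22 °C, with levels of 1617 and 398 CPM in the libraries at 16 °C. AT4G20320 rose from 46.4 to 761 CPM (log2 fold change 4.03 ± 0.58) and AT3G15450 from 46.4 to 542 CPM (3.54 ± 0.60). The edgeR Benjamini-Hochberg adjusted p values were 3.09e-05, 3.09e-05 and 3.96e-04. In all, 9 genes rose and 4 fell, with 23 calls without replicate 1 and 0 without replicate 2 of Col-0 at 16 °C and 21 without replicate 2 of lhp1. With thinned counts there were 0 calls, and with doublets kept AT4G20320 lost its call (0.94). DESeq2 called 0 of the 3057 genes, 260 of which had an unadjusted p under 0.05 in edgeR. FT, the mobile flowering signal made in phloem, was at 17784 CPM at 16 °C and 18316 CPM at 22 °C, a log2 fold change of 0.04 ± 0.29. It is also a leading gene of this cluster.

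Xylem and cambium-like nuclei, 33 of them at 22 °C, had 10 genes higher and 18 lower. BXL1, a beta-xylosidase, rose from 326 to 3662 CPM (log2 fold change 3.71 ± 0.51) and ATCSLA09, a glucomannan synthase, fell by 4.90 ± 0.72 (edgeR, Benjamini-Hochberg adjusted p = 8.20e-09 and 8.77e-08). ATCSLA09 had 3 UMIs at 22 °C against 327, a ratio of 32.0 with a counting interval of 10.9 to 156. The count of 28 was 68 without replicate 2 of Col-0 at 16 °C, and 16 and 13 without replicates 1 and 2 of lhp1. It was 5 with thinned counts, 15 with equal nuclei per library and 16 with at least 400 genes per nucleus. With doublets kept, and at a clustering resolution of 2, edgeR called 0 genes, so BXL1 (0.94 and 1.19) and ATCSLA09 (-6.36 and -6.08) lost their calls. In the reported fit 207 genes had an unadjusted p under 0.05 and DESeq2 called 6.

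In fruit mesophyll-like nuclei TCH4, a cell wall enzyme gene induced by touch, rose from 8.78 to 326 CPM at 22 °C. Its log2 fold change was 5.29 ± 0.43 (edgeR, Benjamini-Hochberg adjusted p = 0.0272), the single call of 13009 genes, lost without either Col-0 library at 16 °C (6.02 and 4.68) and at clustering resolutions of 0.5 and 2 (4.12 and 5.88). The response of TCH4 differed between classes (edgeR, class-by-group test, Benjamini-Hochberg adjusted p = 1.07e-04). The fruit mesophyll-like class joined clusters 2 and 3. Cluster 3, which made up most of the class in lhp1, held 6 and 4 of its nuclei at 16 °C and 55 at 22 °C. Seed coat-like nuclei came from different clusters, with 509 and 142 nuclei of cluster 5 at 16 °C and 32 at 22 °C, and 178, 179 and 175 of cluster 18. There NCED9, which makes the ABA precursor xanthoxin and leads cluster 5 of the class, had 605 and 341 CPM at 16 °C and 98.6 CPM at 22 °C, a log2 fold change of -2.27 ± 0.43 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.124). The edgeR test called 0 genes in seed coat-like, epidermis-like and guard cell-like nuclei, with 1704, 745 and 580 at an unadjusted p under 0.05, where DESeq2 called 78, 19 and 0. Without replicate 2 of Col-0 at 16 °C these 3 classes had 836, 322 and 162 calls, and without replicate 1 guard cell-like nuclei had 239. Without replicate 1 of lhp1, seed coat-like, epidermis-like and fruit mesophyll-like nuclei had 43, 81 and 42 calls, and without replicate 2 of lhp1 fruit mesophyll-like and guard cell-like nuclei had 14 and 10.

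Genes of ABA movement did not pass for temperature over whole libraries or in the named classes. ABCG25, an exporter of ABA, had 202 and 138 CPM in embryo-like nuclei at 16 °C and 62.3 CPM at 22 °C, a log2 fold change of -1.48 ± 0.36 (edgeR, Benjamini-Hochberg adjusted p = 0.0612). It was -0.90 ± 0.32 in endosperm-like, -1.40 ± 0.65 in seed coat-like and -1.58 ± 0.60 in phloem-like nuclei, and -1.20 ± 0.42 over whole libraries. NPF3.1, a transporter of gibberellin and ABA, and NPF2.14 stood at -1.69 ± 0.24 and -1.33 ± 0.33 over whole libraries, and NPF2.13 at -1.58 ± 0.39 in seed coat-like nuclei. In endosperm-like nuclei ABCG31, another ABC transporter of ABA, was at 0.39 ± 0.35, and NCED6, an enzyme of ABA synthesis, at -0.23 ± 0.30. The phosphatidylethanolamine-binding protein gene MFT was at -0.18 ± 0.24 in embryo-like and 0.23 ± 0.27 in endosperm-like nuclei. CYP707A1 was at -0.52 ± 0.26, ABCG40 at -1.38 ± 1.03 and ABCG30 at -0.21 ± 0.67 over whole libraries. Of the 13 ABA transport genes measured over whole libraries, NPF3.1 and NPF2.14 were lower when adjusted over the list alone.

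Between lhp1 and Col-0 at 16 °C, 27 genes rose and 6 fell over whole libraries of 19304 tested. XTH18, a xyloglucan endotransglucosylase and a leading gene of the epidermis-like cluster, had 2 UMIs in Col-0 at 16 °C and 723 in lhp1, a ratio of 314 with a counting interval of 86.5 to 2595, and DREB26, an ERF transcription factor, 3 and 640, a ratio of 185 (63.1 to 900). ESE3, another ERF factor and like DREB26 a leading gene of the mesophyll-like cluster 3, rose from 0.874 to 29.8 CPM (log2 fold change 5.03 ± 0.42, SE, n = 2 per group), LBD39, a regulator of nitrogen responses, from 2.04 to 46.6 CPM (4.57 ± 0.38), and AT2G05540 from 16.0 to 224 CPM (3.80 ± 0.38). AT2G39855 fell by 4.23 ± 0.52, AT1G68600 by 2.52 ± 0.30, AT3G04200 by 2.37 ± 0.22 and GLN1;4, a cytosolic glutamine synthetase, by 2.03 ± 0.21. Adjusted p values of these 9 genes lay between 0.0157 and 0.0493 (edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 415 and 273. The edgeR count was 465 without replicate 1 and 20 without replicate 2 of Col-0 at 16 °C, and 0 without either library at 22 °C or either lhp1 library, so none of these genes kept its call throughout; without replicate 2 at 22 °C, 2900 genes had an unadjusted p under 0.05.

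Wound and touch genes had a median log2 fold change of 1.82 in lhp1 libraries over 10 genes and photosynthesis genes one of 0.76 over 11, while the flavonoid list stood at -0.45 over 14. Camera with a preset correlation gave Benjamini-Hochberg adjusted p of 1.95e-05, 0.00115 and 0.0131, and with an estimated correlation an adjusted p of 0.853 for each. Marker genes of fruit mesophyll stood at 0.66 and those of seed coat at -0.62, with preset adjusted p of 0.0119 and 1.02e-06 and estimated-correlation adjusted p of 0.853 and 0.609. Without replicate 1 of Col-0 at 16 °C the photosynthesis and fruit mesophyll calls were lost, and without replicate 1 of lhp1 the flavonoid and fruit mesophyll calls. The 21 measured floral and flowering regulators kept silent by Polycomb had a median of -0.11. Other medians were -0.09 for ABA synthesis, 0.45 for ABA catabolism, 0.05 for ABA transport, -0.24 for ABA signalling, -0.17 for dormancy regulators, 0.23 for gibberellin genes, 0.52 for cold response, 0.18 for heat response and 0.32 for thermomorphogenesis. They were 0.13 for storage and late embryogenesis, 0.05 for the Polycomb list, whose camera direction was down, 0.02 for the clock, likewise down, and -0.22 for senescence. Marker medians were 0.19 for embryo, 0.28 for endosperm, 0.01 for epidermis, 0.22 for guard cell, 0.32 for phloem, -0.30 for xylem and cambium, -0.52 for lignified layers, 0.61 for dividing cells and 0.21 for replum. The adjusted p of these 22 lists ran from 0.0813 to 0.994.

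In embryo-like nuclei, 7 of 11 measured photosynthesis genes rose in lhp1, among them CAB1, RBCS1A and GAPA, and 10 adjusted over the list alone, with a median of 1.10 (camera, Benjamini-Hochberg adjusted p = 5.23e-23 with the preset and 0.470 with an estimated correlation). All 11 are also markers of fruit mesophyll, which stood at a median of 0.66 over whole libraries, where fruit mesophyll-like nuclei made up 14.6% in Col-0 at 16 °C and 20.96% in lhp1. PORB, which makes chlorophyllide, rose from 45.7 to 240 CPM (log2 fold change 2.35 ± 0.20), LHCB2.3 from 12.4 to 97.6 CPM (3.09 ± 0.29) and ACHT5, a chloroplast thioredoxin, from 4.26 to 74.2 CPM (4.20 ± 0.40), each with an edgeR Benjamini-Hochberg adjusted p of 5.10e-05. CAB1 had 441 and 553 CPM in Col-0 at 16 °C and 1585 and 1715 in lhp1. Of 10 measured flavonoid genes 3 fell, and 6 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.74e-06 with the preset and 0.585 with an estimated correlation). TT7 fell by 1.32 ± 0.23 and FLS1 by 1.41 ± 0.25, both enzymes of flavonol synthesis (edgeR, Benjamini-Hochberg adjusted p = 0.00735 and 0.00763). Other members of the flavonoid list, such as TT10 and TT8, are also seed coat markers, whose median over whole libraries was below 0. ABI5, a transcription factor of ABA response in seeds, fell by 1.56 ± 0.27, GA20OX2, of gibberellin synthesis, by 1.96 ± 0.37 and RDO5, a dormancy regulator, by 1.39 ± 0.31 (edgeR, Benjamini-Hochberg adjusted p = 0.00698, 0.0115 and 0.0300). The DOG1 log2 fold change of -0.55 ± 0.27 did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.419). In all, 190 genes rose and 75 fell of 15046, and DESeq2 called 40 and 11, without ABI5, GA20OX2 or RDO5. The count of 265 was 174 at a clustering resolution of 2, where RDO5 (-1.23) was not called, nor with doublets kept (-1.34) or thinned counts (-1.5985), and 712 without replicate 1 of Col-0 at 16 °C, and 473 and 161 without replicates 1 and 2 of lhp1. Without replicate 2 of lhp1 the calls of FLS1 (-0.98), GA20OX2 (-1.59) and RDO5 (-1.19) were lost.

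Endosperm-like nuclei of lhp1 had 116 genes higher and 66 lower. BT5, a BTB and TAZ domain scaffold protein, rose from 2.50 to 82.4 CPM (log2 fold change 4.45 ± 0.51) and AT5G08350 from 57.1 to 237 CPM (2.19 ± 0.27). AT3G15450 had 2 UMIs in Col-0 at 16 °C and 109 in lhp1, a ratio of 37.6 (counting interval 10.2 to 315). NPF4.1, an ABA importer, fell by 0.82 ± 0.17 and HAI2, an ABA-induced phosphatase, by 2.142 ± 0.44. The edgeR Benjamini-Hochberg adjusted p values were 4.38e-04, 5.33e-04, 2.58e-04, 0.0192 and 0.0177. DESeq2 called 38 higher and 12 lower, without BT5 (4.64), AT3G15450 (5.37) or HAI2 (-2.04), to which it gave no adjusted p. The count of 182 was 96 with thinned counts and 45 with equal nuclei per library, where HAI2 (-2.58 and -1.87) was not called, nor NPF4.1 with equal nuclei (-0.57), doublets kept (-0.53), at least 400 genes per nucleus (-0.54) or a clustering resolution of 2 (-0.63). It was 103 without replicate 2 of Col-0 at 16 °C and 350 without replicate 1 of lhp1. NPF4.1 lost its call without replicate 1 or 2 of Col-0 at 16 °C (-0.82 each), and HAI2 without replicate 1 of Col-0 at 16 °C (-1.51) or replicate 2 of lhp1 (-1.66).

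Fruit mesophyll-like nuclei had 539 genes higher and 360 lower in lhp1 of 13009. Different clusters made up the class: cluster 2 held 587, 958 and 653 of its nuclei in the Col-0 libraries and 177 and 106 in lhp1, and cluster 3 held 6, 4 and 55 in Col-0 and 962 and 879 in lhp1. Of 9 measured wound and touch genes 7 rose, and all 9 adjusted over the list alone, with a median log2 fold change of 2.95. TCH4 rose from 8.78 to 1020.4 CPM (6.94 ± 0.40), TCH3, a calmodulin-like protein gene, from 12.7 to 201 CPM (4.13 ± 0.52), WRKY33, a defence transcription factor, from 24.0 to 299 CPM (3.68 ± 0.51) and JAZ1, a repressor of jasmonate signalling, from 63.0 to 346 CPM (2.50 ± 0.48), with edgeR Benjamini-Hochberg adjusted p of 0.00167, 0.00560, 0.00744 and 0.0217. Camera gave the list an adjusted p of 4.15e-08 with the preset and 0.534 with an estimated correlation. MYB77, a transcription factor of auxin response, rose by 4.29 ± 0.29 on the log2 scale and EXLA1, an expansin-like protein gene, by 5.37 ± 0.38, while the zinc finger gene ZFP8 fell by 5.78 ± 0.38 (edgeR, Benjamini-Hochberg adjusted p = 0.00167 each).

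Of 17 measured clock genes in this class 4 fell and 3 rose, and 7 fell and 3 rose adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.149 with the preset and 0.971 with an estimated correlation). CCA1, RVE8 and LNK2 fell by 3.13 ± 0.38, 3.02 ± 0.34 and 1.53 ± 0.25 on the log2 scale in lhp1, as did PRR9, while LUX rose by 2.56 ± 0.41, as did CHE and TOC1 (edgeR, Benjamini-Hochberg adjusted p = 0.00482, 0.00412, 0.0120 and 0.0117 for the 4 with values). CCA1 stood at 287 and 289 CPM in Col-0 at 16 °C, 135 at 22 °C, and 46.6 and 19.5 in lhp1. Of 18 floral and flowering regulators kept silent by Polycomb, AGL19, a flowering activator, rose from 1 to 88 UMIs, a ratio of 38.4 (counting interval 6.71 to 1533), and SOC1, SEP2 and STK fell by 1.51 ± 0.23, 1.13 ± 0.25 and 2.42 ± 0.55 (edgeR, Benjamini-Hochberg adjusted p = 0.00894, 0.0107, 0.0387 and 0.0409). ABA genes that fell were ABA1, of xanthophyll conversion (-1.79 ± 0.26), NPF2.12 (-1.81 ± 0.29), NPF2.13 (-1.91 ± 0.37), NPF5.1 (-1.56 ± 0.32) and NCED6 (-2.36 ± 0.51), with edgeR Benjamini-Hochberg adjusted p of 0.00833, 0.0120, 0.0225, 0.0270 and 0.0340. Of 11 ABA transport genes 3 fell, and 5 fell and 1 rose adjusted over the list alone. STK is also a seed coat marker, and seed coat markers had a median below 0 over whole libraries. NCED6 is also on the endosperm marker list, so RNA from other nuclei was not excluded for it. NPF5.1 is a leading gene of cluster 26, of the seed coat-like class, which held 39 and 87 nuclei in Col-0 at 16 °C and 7 and 0 in lhp1. CYP707A2 was a leading gene of cluster 2 and is not compared within the class. Over whole libraries it stood at 56.4 CPM in Col-0 at 16 °C and 9.97 in lhp1 (log2 fold change -2.51 ± 0.31, edgeR Benjamini-Hochberg adjusted p = 0.0512). The 899 calls became 592 without replicate 2 of lhp1 and 230 at a clustering resolution of 0.5, where TCH3 (0.94), WRKY33 (0.77), JAZ1 (1.56), LNK2 (-1.40), LUX (2.21), ABA1 (-1.62), NCED6 (-2.21), NPF2.13 (-1.79), NPF5.1 (-1.45), SEP2 (-1.04) and STK (-2.58) were no longer called. At a resolution of 2 there were 476, without WRKY33 (0.03), JAZ1 (0.85), NCED6 (-2.52), SEP2 (-1.13) or STK (-2.003), and with doublets kept WRKY33 (2.51) and JAZ1 (1.83) lost their calls. NCED6, SEP2 and STK also lost theirs with equal nuclei and with thinned counts, STK with at least 400 genes per nucleus (-2.07), and in DESeq2, as did NPF2.12 in DESeq2 (-1.80). Calls were lost without replicate 2 of Col-0 at 16 °C for JAZ1 (1.94), LUX (2.48), STK (-1.85), NPF2.12 (-1.62), NPF5.1 (-1.33) and NCED6 (-2.02), without replicate 1 for SEP2 (-0.84) and NCED6 (-2.60), and without replicate 1 of lhp1 for SEP2 (-1.16) and STK (-2.19). Without replicate 2 of lhp1 they were lost for LNK2 (-1.34), SOC1 (-1.41), SEP2 (-1.11), STK (-2.70), NPF2.13 (-1.92), NPF5.1 (-1.20) and NCED6 (-1.94).

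Epidermis-like nuclei of lhp1 had 167 genes higher and 58 lower. AT2G05540 rose from 19.02 to 2381 CPM (log2 fold change 7.03 ± 0.56) and KAN2, a regulator of organ polarity, fell by 3.71 ± 0.40 (edgeR, Benjamini-Hochberg adjusted p = 6.30e-04 and 0.00167). AT2G05540 was higher in 6 classes and most abundant in cluster 15, so RNA from other nuclei was not excluded for it. XTH18, a leading gene of the cluster, is not compared within it. Phloem-like nuclei had 67 genes higher and 77 lower. SPL4, a transcription factor of the floral transition, rose from 207 to 2382 CPM (3.56 ± 0.38), AT2G39855 fell by 5.25 ± 0.45, RD29A by 3.83 ± 0.55 and ELIP1, a light stress protein gene, by 3.59 ± 0.56 (edgeR, Benjamini-Hochberg adjusted p = 1.35e-08, 6.02e-11, 6.51e-06 and 2.34e-05). FT was at -0.13 ± 0.24. Without replicate 1 of Col-0 at 16 °C, epidermis-like nuclei had 0 calls, losing AT2G05540 (6.25) and KAN2 (-3.49), and without replicate 2 they had 642. Without replicate 2 of lhp1 they had 26, not with KAN2 (-3.51), with doublets kept 133, and in DESeq2 88. The phloem-like count of 144 was 16 with thinned counts, which ended the calls of RD29A (-3.525) and ELIP1 (-3.61), 25 in DESeq2, without RD29A (-3.56), and 3 without replicate 2 of Col-0 at 16 °C, which ended the calls of RD29A (-4.51) and ELIP1 (-4.19), 67 without replicate 1 of Col-0 at 22 °C and 62 without replicate 2 of lhp1.

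Guard cell-like nuclei had 46 genes higher and 17 lower, with AK3, SULTR2;1, a sulfate transporter, and AT3G15450 at 3.57 ± 0.46, 3.67 ± 0.53 and 2.27 ± 0.33 on the log2 scale, and AT3G06435, which fell by 4.14 ± 0.40. Xylem and cambium-like nuclei had 38 higher and 28 lower. The dehydrin gene COR47 rose from 613 to 2642 CPM, ERD10, another dehydrin gene, rose by 2.33 ± 0.47 on the log2 scale, and ATCSLA09 fell by 4.88 ± 0.51 (edgeR, Benjamini-Hochberg adjusted p = 1.54e-04, 2.28e-04 and 5.75e-15). Dividing cell-like nuclei had 30 higher and 13 lower, and 6 of 9 photosynthesis genes rose, with CAB2 at 2.05 ± 0.32 and CAB1 at 1.83 ± 0.29 (edgeR, Benjamini-Hochberg adjusted p = 3.10e-07 each). Fruit mesophyll markers, to which both belong, stood at a median of 0.66 over whole libraries. Seed coat-like nuclei had 7 higher and 6 lower. There AT1G75945 had 75 UMIs in lhp1 and 0 in Col-0 at 16 °C, at least 30.5-fold higher, and AT5G37478 fell by 6.42 ± 0.40 (edgeR, Benjamini-Hochberg adjusted p = 0.0485 and 0.00148). The mix of clusters in this class differed between the groups. Cluster 26 held 39 and 87 of its nuclei in Col-0 at 16 °C and 7 and 0 in lhp1. The flavonoid oxidase gene TT10, a seed coat marker most abundant in cluster 1, was lower in 8 of the 9 classes, and EXT3 and GER2, also most abundant there, in 6. The share of cluster 1 was 15.04% in Col-0 at 16 °C and 5.71% in lhp1. AT1G62000 and AT1G62080 were lower in 8 classes, at levels in Col-0 at 16 °C that were alike in most of them, such as 681 CPM in guard cell-like and 748 CPM in dividing cell-like nuclei for AT1G62000.

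These counts moved with single libraries and with the processing. Guard cell-like nuclei had 507 and 342 calls without replicates 1 and 2 of Col-0 at 16 °C, 1 without replicate 1 at 22 °C, and 0 and 97 without replicates 1 and 2 of lhp1. AK3, SULTR2;1 and AT3G15450 lost their calls there without replicate 1 at 22 °C or replicate 1 of lhp1 (3.24, 3.91 and 2.29 without the latter), and AT3G06435 without replicate 1 of lhp1 (-4.21). At a clustering resolution of 2 edgeR called 0 genes there, so AK3 (3.56), SULTR2;1 (3.65), AT3G15450 (2.58) and AT3G06435 (-4.25) lost their calls, where the reported fit had 1004 at an unadjusted p under 0.05 and DESeq2 called 15. Thinned counts gave 9, the strict low-count filter 29, equal nuclei per library 174 and a resolution of 0.5 125. Xylem and cambium-like nuclei had 111 calls without replicate 2 of Col-0 at 16 °C, 17 without replicate 1 at 22 °C, and 22 and 14 without replicates 1 and 2 of lhp1, where COR47 (1.87) and ERD10 (1.05) lost theirs in turn, ERD10 also without replicate 1 at 22 °C (2.34). They had 12 at a clustering resolution of 2, where COR47 (1.75) and ERD10 (2.07) were not called, nor with doublets kept (1.62 and 1.7994), 14 with thinned counts, and 9 in DESeq2, the last 2 without ERD10 (2.23 and 2.21). Dividing cell-like nuclei had 28 without replicate 1 of Col-0 at 16 °C, 11 without replicate 1 at 22 °C, and 19 and 21 without the lhp1 libraries. They had 6 with thinned counts, 3 with equal nuclei per library, which ended the calls of CAB1 (1.54) and CAB2 (1.9973), and 2 in DESeq2, without CAB2 (2.0033). Seed coat-like nuclei had 461, 138, 74, 137 and 0 without replicates 1 and 2 of Col-0 at 16 °C, replicate 1 at 22 °C and replicates 1 and 2 of lhp1. With doublets kept they had 0, against 1440 at an unadjusted p under 0.05 and 82 in DESeq2 in the reported fit, and AT1G75945 and AT5G37478 lost their calls there, at clustering resolutions of 0.5 and 2 and with at least 400 genes per nucleus. AT1G75945 also lost its call with equal nuclei, thinned counts, library totals, the strict low-count filter and DESeq2.

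**Figure D2:**
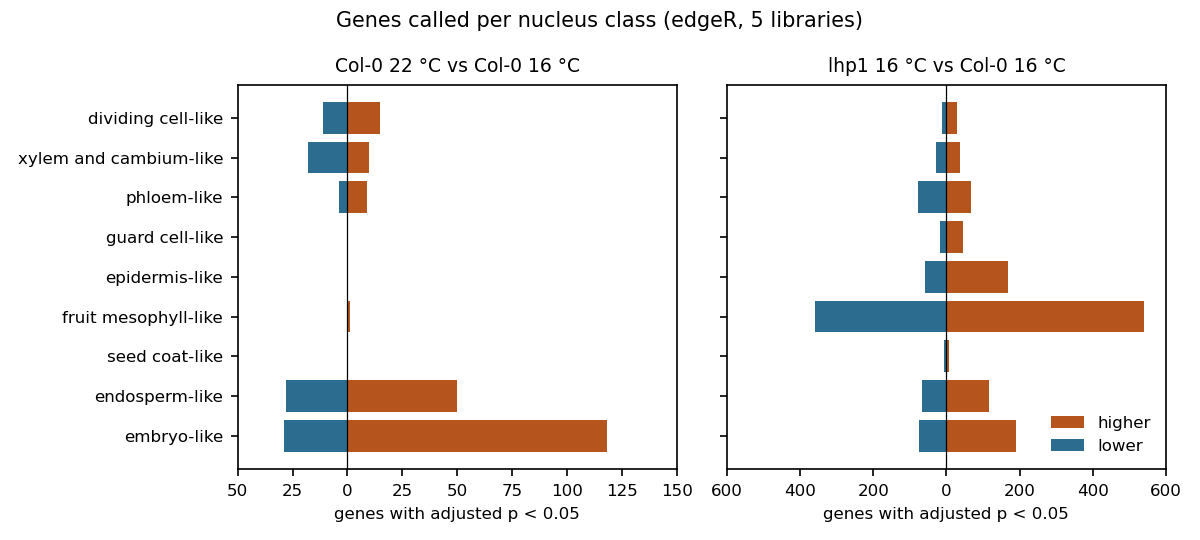
Number of genes with an adjusted p under 0.05 (horizontal axis, edgeR quasi-likelihood test, 5 libraries) that were higher (right of 0) or lower (left of 0) in each nucleus class (vertical axis), for Col-0 at 22 °C against 16 °C and for lhp1 against Col-0 at 16 °C. The horizontal scales differ; embryo-like nuclei had 118 higher and 29 lower genes at 22 °C, and fruit mesophyll-like nuclei 539 and 360 in lhp1.

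**Figure D3:**
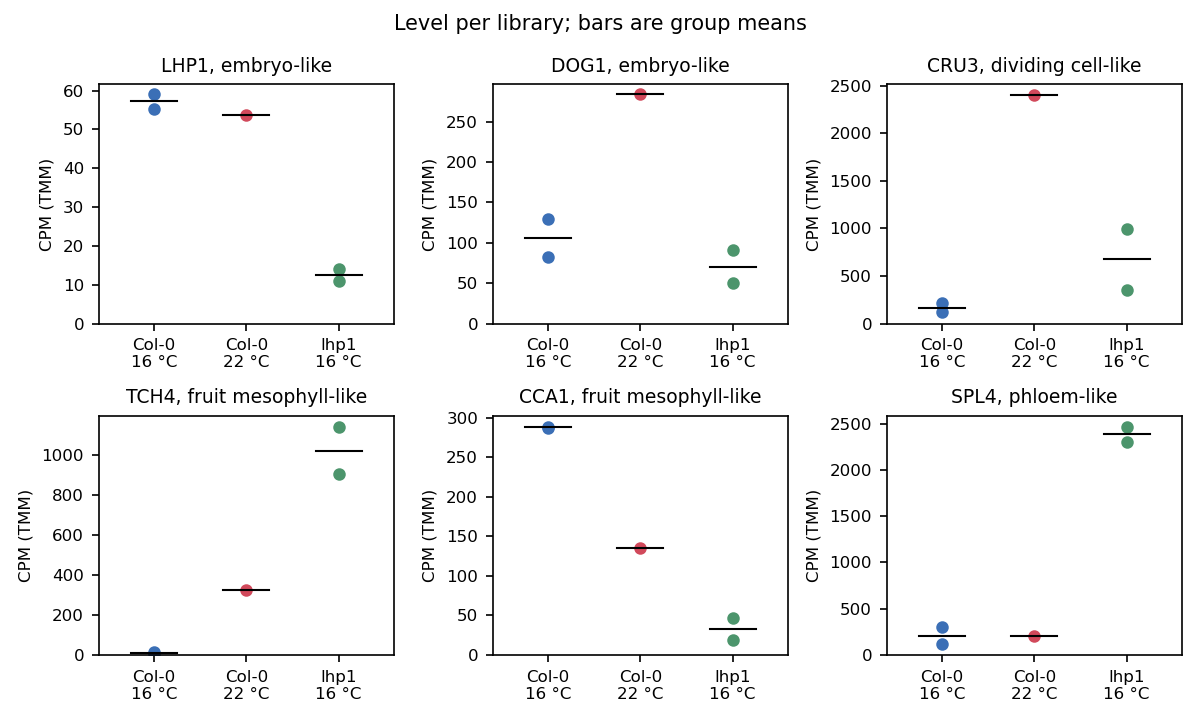
Level of 6 genes in 1 nucleus class each (vertical axes, CPM with TMM scaling) in the 3 groups (horizontal axes). Points are libraries, 2 for Col-0 at 16 °C, 1 at 22 °C and 2 for lhp1, and black bars are group means; DOG1 in embryo-like nuclei reached 284 CPM at 22 °C against 82.5 and 130 CPM at 16 °C, and SPL4 in phloem-like nuclei was at 2382 CPM on average in lhp1.

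ABA and dormancy genes of the fixed set were also read in lhp1 where they did not pass. ABCG25 was at 0.53 ± 0.24 in embryo-like and -0.07 ± 0.21 in endosperm-like nuclei, ABCG31 at 0.70 ± 0.24 in endosperm-like nuclei, and MFT at -0.61 ± 0.20 in embryo-like and -0.62 ± 0.22 in endosperm-like nuclei. NCED9 was at 1.23 ± 0.31 in seed coat-like nuclei, with 1120.1 and 1101 CPM in lhp1, where cluster 5, which it leads, held 208 of 329 and 451 of 609 nuclei of the class, against 509 of 901 and 142 of 462 in Col-0 at 16 °C. CYP707A1, ABCG40 and ABCG30 were at 0.32 ± 0.25, 2.137 ± 0.78 and 1.17 ± 0.61 over whole libraries, and NCED6 at -0.89 ± 0.33.

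Genes called in both comparisons were counted. Summed over the 9 classes, with a gene counted once per class, 44 rose and 10 fell in both, among them AT3G15450 in endosperm-like nuclei. Opposite calls numbered 2 in embryo-like, 5 in endosperm-like and 1 in phloem-like nuclei, with none in the other classes. In embryo-like nuclei 23 rose in both, where independent lists would share 1.49. Simulated groups with a common control and no changed gene shared 0.2. Few genes can be called in such groups, so the 0.2 gives no chance level for the 23. The covariance of the log2 fold changes was 0.128 against 0.0934 in the simulations in embryo-like nuclei, 0.353 against 0.111 in fruit mesophyll-like, 0.420 against 0.168 in guard cell-like and 0.588 against 0.164 in xylem and cambium-like nuclei, but -0.0954 against 0.0961 in seed coat-like nuclei and 0.0753 against 0.115 over whole libraries. The correlation of the log2 fold changes gave another picture. It was below the simulations in embryo-like (0.277 against 0.426) and fruit mesophyll-like nuclei (0.385 against 0.427). It was also below them in endosperm-like, seed coat-like, epidermis-like, phloem-like and dividing cell-like nuclei and over whole libraries. Guard cell-like (0.556 against 0.467) and xylem and cambium-like nuclei (0.470 against 0.362) lay above. Both comparisons use the same 2 libraries of Col-0 at 16 °C, which cannot be split, so part of any excess may come from them. The 54 shared calls became 277 and 411 without replicates 1 and 2 of Col-0 at 16 °C, and 154 and 117 without replicates 1 and 2 of lhp1.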

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

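The tests of shallow depth, of free RNA in place of nuclei, of a label swap and of free RNA from cluster 1 for 8 genes were chosen only after the result was seen, as were the 5 libraries of the class comparisons.

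Responses differed between nucleus classes for 78 genes in the temperature comparison and for 852 in lhp1, of 12126 tested in 9 classes (edgeR quasi-likelihood, class-by-group terms with the library as a block, Benjamini-Hochberg adjusted). The first count was 123 without replicate 1 and 548 without replicate 2 of Col-0 at 16 °C, and the second was 231 without replicate 2 of lhp1. Organelle-encoded RNA, outside the tested genes, made up 1.69% and 2.94% of UMIs in the libraries at 22 °C, above the 1.39% and 1.481% of Col-0 at 16 °C. Parting the 4 libraries of Col-0 at 16 °C and lhp1 in 3 ways gave 1759 class-level calls for the real groups and 0 at most for the others (edgeR). These 3 ways are too few for a share under 0.05. In the others each part held 1 library of Col-0 and 1 of lhp1, so any genotype difference widened the spread within parts. Few calls could arise there, so the 0 gives no false-call level for the 1759.

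Barcodes of replicate 2 of Col-0 at 22 °C differed little from one another. Low depth alone is argued against, since the lowest median index of the other libraries, thinned to 400 UMIs, was 1.39 against 1.04 here. RNA from pollen is argued against by 5 pollen genes not looked at before, with a median ratio of 0.426 to the other libraries, and by VGD1 at 1.28 CPM. However, MGH3, with 5 UMIs, and TPPI were highest here. The 5 genes had only 1, 2, 0, 0 and 5 UMIs in this library, so their ratio rests on few counts. The ratio also pools libraries that held pollen RNA themselves. ANX2, among the 5, had 56 and 51 UMIs in replicate 1 of Col-0 at 16 °C and of lhp1, against 1, 3 and 1 in the rest. A ratio under 1 therefore does not show less pollen RNA here than in the libraries with little of it. The 49 nuclei of other libraries in its cluster were led by pollen genes such as VGD1 and BGAL11. Free RNA in place of nuclei cannot be told apart from other causes, because the index of 1.07 at full depth is the pattern itself and so decides nothing. No biological explanation was tested.

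Replicate 2 of Col-0 at 16 °C lay nearer to replicate 1 at 22 °C (r = 0.934 across genes) than to replicate 1 of its own group (0.863). A swap of labels between both Col-0 groups cannot be told apart from other causes: each library at 22 °C correlated better with replicate 2, by 0.136 or more, but for a swap that would give this pattern only replicate 2 at 22 °C decides, and its barcodes hardly differ. A single wrong label needs no partner and also stays open. A different mix of cell types may account for the pattern, because in only 2 of 9 classes, seed coat-like and phloem-like, was replicate 2 nearer to the library at 22 °C, and clusters 11 and 14 held 518 and 346 nuclei in it against 0 and 8 in replicate 1. Later seeds in replicate 2 stay open, as storage genes in embryo-like nuclei had a median log2 ratio of 0.43 with an SD of 0.792, higher in 12 of 16. Growth temperature also stays open, as untested.

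In 12 genes, among them TT10, EXT3, GER2 and MYB107, RNA was lower in lhp1 in 4 or more classes. Free RNA from one source would keep the genes at 1 ratio in every class, which for the 12 together is argued against by a median SD over genes of 2.79 on the log2 scale, with GLN1;4 at 12.7 CPM in cluster 1 against a median of 156 CPM elsewhere. For the 8 genes highest in cluster 1 the SD was 0.951, between both bounds, so free RNA from this cluster, with 1039 and 644 nuclei in Col-0 at 16 °C and 472 and 121 in lhp1, cannot be told apart from other causes. A change within each class, the effect of the genotype, may also be at work: the SD over classes of a gene's log2 fold change was 0.41, under the bound of 0.5 that had been set against it beforehand. That bound was wrong, because an equal fall in each class gives equal folds too, so this value decides nothing. Another 9 genes, among them AT2G05540, were higher in lhp1 in 4 or more classes, with an SD over genes of 1.83 and over classes of 0.697, and no explanation was tested for them.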

How the results depend on the processing

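The 5-library fits of classes, shares and shared calls, and every refit of the class-difference test, were chosen after the data were seen. The 0 calls for temperature over whole libraries (edgeR; 3508 genes at an unadjusted p under 0.05) became 844 with DESeq2, 473 with no low-count filter and 4 with counts thinned to the smallest library, and ran from 0 to 434 with single libraries left out, the latter without replicate 2 of Col-0 at 16 °C. The 293 class-level calls for temperature became 178 with DESeq2, 2246 with no filter, 865 with only the libraries compared, 166 with doublets kept, and 621 and 2195 without replicates 1 and 2 of Col-0 at 16 °C and 949 and 741 without those of lhp1. The 33 whole-library calls in lhp1 became 65 with a replicate block, 688 with DESeq2, 529 with no filter and 0 with only the libraries compared. They became 465 and 20 without replicates 1 and 2 of Col-0 at 16 °C, and 0 without any 1 of the other 4 libraries. The 1900 class-level calls in lhp1 became 962, 5283 and 1259 with DESeq2, no filter and Leiden resolution 0.5, and ran from 1153, without replicate 2 of lhp1, to 2773. LHP1 lost its call at -2.34 with only the libraries compared, and ran from -2.46 to -2.24 with libraries left out, called only without replicate 1 of Col-0 at 16 °C. The 10 lists called for temperature and 5 for lhp1 became 0 and 0 by camera with an estimated correlation and 0 and 0 by fry, while leaving out libraries gave 7 to 13 and 4 to 10, the 10 without replicate 2 of lhp1. Shared calls, 54 in all, were 277 and 411 without replicates 1 and 2 of Col-0 at 16 °C and 154 and 117 without those of lhp1. Genes that differed between classes ran from 79 to 548 for temperature and 231 to 990 for lhp1. Fits without a library assume that the lone library of its group varies as the other groups do, and fits with only the libraries compared have fewer residual degrees of freedom. The cause of the other changes was not tested. Direction was checked only for the genes taken by the naming rule and for the lists, where no called direction reversed in the alternatives run. The balance of calls over all genes did shift. Class-level temperature calls were 203 higher and 90 lower in edgeR, and 72 and 106 in DESeq2. Class shares had 0 calls in each alternative run for them (edgeR, 0 at an unadjusted p under 0.05 in the reported fit; no other tool was run). Of the gene results, 249 stayed on their side of the threshold with DESeq2, while 63 lost and 17 gained a call, and with Leiden resolution 2 the counts were 213, 38 and 5. The guard cell class could not be compared with at least 400 genes per nucleus or with doublets kept. With the replicate block the class-level counts were 342 and 2286 and the shared calls 78, and 26 gene calls ended. For temperature it moved embryo-like calls from 147 to 38, endosperm-like from 78 to 210, dividing cell-like from 26 to 15, fruit mesophyll-like from 1 to 8, epidermis-like from 0 (edgeR; 745 at an unadjusted p under 0.05; DESeq2 19) to 58 and xylem and cambium-like from 28 to 0. For lhp1 it moved embryo-like from 265 to 180, endosperm-like from 182 to 388, fruit mesophyll-like from 899 to 1113, epidermis-like from 225 to 443, guard cell-like from 63 to 18, phloem-like from 144 to 106, dividing cell-like from 43 to 35, seed coat-like from 13 to 2 and xylem and cambium-like from 66 to 1. With library totals in place of TMM, calls higher and lower in lhp1 went from 116 and 66 to 97 and 101 in endosperm-like and from 167 and 58 to 197 and 130 in epidermis-like nuclei, and for temperature from 9 and 4 to 11 and 11 in phloem-like and from 10 and 18 to 16 and 16 in xylem and cambium-like nuclei. Without the low-count filter, calls for temperature were 578 in embryo-like, 173 in endosperm-like, 786 in seed coat-like, 401 in fruit mesophyll-like, 176 in epidermis-like, 95 in guard cell-like and 11 in xylem and cambium-like nuclei, and for lhp1 732, 373, 808, 2027, 696, 444 and 24, in the same order. With the strict filter they were 13 in xylem and cambium-like nuclei for temperature, and for lhp1 1 in seed coat-like, 114 in epidermis-like and 32 in xylem and cambium-like nuclei. Equal nuclei per library gave 27 phloem-like and 25 epidermis-like calls for temperature, and 351 epidermis-like and 23 xylem and cambium-like calls for lhp1. Replicate numbers were not shown to pair libraries: same-numbered deviations correlated at 0.0453 between the Col-0 groups, -0.466 between Col-0 at 16 °C and lhp1, and -0.0407 between Col-0 at 22 °C and lhp1, and nothing was crossed. In simulations for temperature, with changed genes of at least 10 CPM, 4 of 100 2-fold changes were recovered over whole libraries. In the shallower sums of embryo-like nuclei 29 were recovered. The common coefficients of variation were 26.65% and 14.5%, so depth alone did not order what was recovered. Thinning whole libraries moved the lhp1 calls from 33 to 46.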

Other observations

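The pollen, suberin and sugar starvation lists were written, and the 5 libraries of the cluster comparisons chosen, after the data were seen. Genes of suberin synthesis and export set the libraries apart. GPAT5, an acyltransferase gene, stood at 2.54 and 343 CPM in the libraries of Col-0 at 16 °C, 417 and 193 CPM at 22 °C, and 24.0 and 4.25 CPM in lhp1, without TMM scaling. In the same order, ABCG20, for a suberin transporter, stood at 2.78 and 506, 420 and 479, and 45.3 and 6.86 CPM, CYP86B1 at 64.1 and 870, 841 and 591, and 108 and 21.9 CPM, and ASFT at 379 and 1196, 1568 and 1442, and 287 and 66.4 CPM. FAR4 had 0 and 1146, 1381 and 242, and 27 and 6 UMIs. FAR1, FAR5, CYP86A1, KCS17, ABCG2 and ABCG6 were likewise higher in replicate 2 of Col-0 at 16 °C and both libraries at 22 °C than in the other 3, while MYB107 differed less, with 803 and 963, 881 and 640, and 457 and 126 CPM. FAR4, FAR5, KCS17 and MYB107 had been seen before.

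Each gene on the sugar starvation list stood higher in both libraries at 22 °C and in both of lhp1 than in both of Col-0 at 16 °C without TMM scaling, with the exception that DIN10 overlapped in lhp1 once TMM was applied. A gap of this kind in a given direction arises by chance in 1 of 6 ways to part 4 libraries, both comparisons share the same controls, and AT3G15450, DRM1, DRM2 and BT5 had been seen before. Some gaps rested on few UMIs: BT2 had 3 and 1 in Col-0 at 16 °C and 6 and 1 at 22 °C. DIN6 had 1 and 1 in Col-0 at 16 °C and 10 and 5 in lhp1. Over whole libraries only AT3G15450 and BT5 passed, in lhp1. AT3G15450 stood at 25.7 and 36.5 CPM in Col-0 at 16 °C, 228 and 252 CPM at 22 °C, and 199.6 and 206 CPM in lhp1. Among genes not seen before, TPS11, for a trehalose phosphate synthase-like protein, stood at 25.5 and 39.2, 84.4 and 106, and 111 and 99.3 CPM, the sugar transporter gene STP1 at 17.2 and 28.7, 89.1 and 128, and 59.02 and 89.8 CPM, and SEN1 at 4.36 and 6.39, 21.2 and 45.0, and 23.3 and 13.0 CPM. DRM1 stood at 24.9 and 21.5, 132 and 236, and 32.5 and 38.4 CPM, and DIN10 at 308 and 371, 460 and 538, and 456 and 380 CPM.

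Clusters without a name also changed. In cluster 1, 185 genes were higher and 108 lower at 22 °C by edgeR, against 26 and 27 by DESeq2. There BRU6, an auxin-induced gene, rose from 10.1 to 113 CPM at 22 °C (log2 fold change 3.51 ± 0.40, SE, 1 library against 2) and the lipid transfer protein gene LTP4 fell by 2.302 ± 0.34, while in lhp1 CAX3, a calcium exchanger gene, rose by 1.69 ± 0.16 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.86e-05, 9.20e-04 and 1.25e-05). In cluster 16, led by the glucosinolate genes MAM1 and CYP79F1, 7 of 9 wound and touch genes rose in lhp1, with WRKY40 at 3.22 ± 0.40 and TCH4 at 4.23 ± 0.54 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.77e-12 and 5.92e-12). NPF3.1, a gibberellin and ABA transporter gene, had 2 UMIs there at 22 °C against 74 at 16 °C, a ratio of 35.0 with a counting interval of 9.36 to 295. In cluster 12, which shares embryo and epidermis markers, GPT2, for a plastid glucose phosphate transporter, fell by 3.87 ± 0.47 at 22 °C and by 3.77 ± 0.35 in lhp1, and ECP63 rose by 3.46 ± 0.46 at 22 °C (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.02e-06, 6.35e-10 and 5.07e-06). In cluster 10 the ABA importer gene ABCG40 rose by 3.80 ± 0.69 in lhp1, and in cluster 9, nearest to the endosperm list, the dormancy regulator RDO5 fell by 2.92 ± 0.39 there (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.16e-05 and 5.57e-05). In each of these genes the libraries compared did not overlap. For temperature DESeq2 called 0 genes higher, ECP63 thus not among them, and 1 lower in cluster 12, where edgeR called 72 and 25 and had 892 at an unadjusted p under 0.05, and 1 and 1 in cluster 16, where edgeR called 74 and 35. In lhp1 it called 48 and 18 in cluster 16, 8 and 4 in cluster 12, 1 and 0 in cluster 10, 17 and 12 in cluster 9 and 19 and 6 in cluster 1, against 297 and 106, 88 and 44, 11 and 7, 136 and 105, and 77 and 35 by edgeR. These clusters were not refitted with single libraries left out.

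TPPI, a trehalose phosphate phosphatase gene, stood at 1192 CPM in replicate 2 of Col-0 at 22 °C and between 5.29 and 23.0 CPM in the other libraries. The pollen gene VGD1 stood at 53.6 and 2.52 CPM in Col-0 at 16 °C, 1.18 and 1.28 CPM at 22 °C, and 29.7 and 1.53 CPM in lhp1. Each of the 10 genes on the pollen list had UMIs in at least 1 library other than replicate 2 of Col-0 at 22 °C.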
